A study of Mus musculus with 6 samples.

How the data were processed

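The deposited table holds 27131 genes by 6 libraries of estimated counts (fragments assigned per gene, not scaled to depth), which the authors made with Cuffdiff 2.1.1, per the submitters' processing notes. The same notes name FastQC 0.10.0, cutadapt, TopHat2 2.0.9, Bowtie2 2.1.0 and Cufflinks, with the genome build mm10; the gene annotation, read filters and strand setting are not given in the sources used here. Total RNA was extracted with Trizol from flash-frozen muscle and prepared with a TruSeq mRNA kit, per the labels' protocols, and the table holds 1 column per mouse. Between 5.38% and 5.96% of the values in a library were fractional, and all were rounded to whole numbers before testing. Where an estimate divides fragments between overlapping genes or close copies, the division can move counts from one gene to another.

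Groups were taken from the genotype label, with 3 WT and 3 113Q mice of 14 weeks. The labels name separate mice, and no batch or litter, so each library counted as its own sample. Counts were compared between groups with edgeR 4.0.16 in R 4.3.3, 113Q minus WT: genes were filtered with filterByExpr (minimum count 10), libraries were scaled with TMM factors, and a robust quasi-likelihood F test (two-sided) was adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The TMM factors were 0.775, 0.768 and 0.794 in WT and 1.32, 1.27 and 1.26 in 113Q, so the factor follows the group and a change in overall RNA content cannot be seen in these values. CPM are TMM-scaled throughout. The floor is 3 counts over the libraries of a group; in a single library 3 counts correspond to 0.0888, 0.0566 and 0.0577 CPM in WT and 0.0335, 0.0335 and 0.0322 CPM in 113Q; this floor and the exact 95% interval given for Cyp17a1 cover counting error only. The common biological coefficient of variation was 24.2%.

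Gene lists (25 of pathways and 14 of cell types) were fixed before the data were examined, as were the tests, most of the other settings and the rule for genes to name. The list of mitochondrially encoded transcripts matched no gene of the table, and 38 lists with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The genes to name were the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, leaving out uncharacterised and small RNA symbols; up to 4 members of each pathway list and up to 2 of each cell type list with the smallest p; and Xist and Ddx3y. Other genes are said to have been chosen after their values were seen. Coordinates and overlaps come from GENCODE mouse release M21 on the same assembly as mm10.

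The scripts were tested on simulated data for this comparison, with 200 genes changed among 16693 tested. The edgeR test recovered 22.4% of the genes changed 1.5 times, 58.2% of those changed 2 times and 90.9% of those changed 4 times. Of its 134 calls, 20 (14.9%) were unchanged genes, above the nominal 5%. For DESeq2 1.42.0 and limma voom these shares were 29.1% and 9.01%. Such a share depends on how many genes change. Far fewer were changed in the simulation than the 5869 of 16960 called in the data. The share of false calls among the genes called in the data is therefore not known from it.

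Alternatives were DESeq2, limma voom with quality weights, RLE and upper-quartile factors, library totals alone, other filters on low counts, unrounded values, no robust estimation, leaving out each mouse, a replicate block, other thresholds, a test against a fold of 1.2, and for lists an estimated correlation, fry and cameraPR. Added after seeing the data were a term for libraries with epithelial transcripts (Epcam of at least 1 CPM), fits to only the libraries with or without them, and removal of a trend on GC content and transcript length (known for 98.0% of tested genes). Protein, muscle weight and reads were not analysed here.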

Results

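Messenger RNA was sequenced from the levator ani/bulbocavernosus muscle, a pair of androgen-sensitive pelvic muscles of the male mouse, at 14 weeks of age. The mice were 3 wild-type animals (WT) and 3 animals labelled 113Q from a knock-in model of SBMA (spinal and bulbar muscular atrophy), a disease of motor neurons and muscle. The estimated counts summed to 43581087, 68983982 and 65405514 in the WT libraries and to 67897870, 70531556 and 73873481 in the 113Q libraries. The 20 most abundant genes held 30.8%, 32.7% and 31.5% of the counts in the WT libraries and 14.2%, 15.1% and 15.7% in the 113Q libraries. The comparison of 113Q with WT asks which transcripts of this muscle differ in the knock-in model.

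In 113Q muscle, all 19 fast fibre genes and 26 of 30 glycolysis and glycogen genes tested were lower. The camera adjusted p of these lists was 2.38e-14 and 2.94e-12 at the preset correlation, but 0.211 and 0.373 with an estimated correlation. Higher were 6 of 10 satellite cell markers and the muscle acetylcholine receptor transcript Chrna1. The satellite cell list had a camera adjusted p of 0.00307 at the preset correlation, but 0.455 with an estimated correlation. Myh1, a fast myosin heavy chain, fell from 35740 ± 7079 CPM (counts scaled to library size with TMM factors; mean ± SD, n = 3) in WT to 1530 ± 45.1 in 113Q (n = 3), 23.4 times lower. Mb, the oxygen-binding protein myoglobin, fell from 12230 ± 1606 to 232.7 ± 23.5 CPM, and Slc2a4, the insulin-responsive glucose transporter, fell from 816.5 ± 99.4 to 180.4 ± 3.39 CPM. Chrna1, the acetylcholine receptor alpha subunit, rose from 25.3 ± 4.48 to 115.3 ± 7.20 CPM, and Myf5, a myogenic transcription factor, rose 4.53 times. Markers of other tissues also differed between libraries: the smooth muscle actin Acta2 was at 46.4, 126 and 184 CPM in WT and 867, 566 and 425 CPM in 113Q, and the epithelial gene Epcam was at 0, 3.83 and 0.0385 CPM in WT and 0, 8.29 and 10.2 CPM in 113Q.

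The Y-linked gene Ddx3y was at 73.5 ± 4.81 CPM in WT and 67.6 ± 5.52 CPM in 113Q, and its difference did not pass the test (edgeR adjusted p = 0.335). Xist, which is transcribed from the inactive X chromosome, summed to 9.07 estimated counts over the WT libraries and 0.407 over the 113Q libraries. Of the 4 tested sex markers 0 passed in edgeR, DESeq2 or voom and 0 had an unadjusted p below 0.05 in edgeR; Kdm5d, also Y-linked, had an edgeR adjusted p = 0.123.

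Of 16960 genes tested, 5869 differed at an adjusted p below 0.05, with 2791 higher and 3078 lower in 113Q. A change of at least 2 times was found for 904 higher and 886 lower genes. With library totals alone, 11015 were higher and 710 lower, a share of 93.9% higher against 47.6%. That scaling moved the median log2 fold change of all genes by 0.72, and changes are given relative to the other genes throughout. The groups did not overlap for 8459 genes, 49.9% of those tested, where chance gives 10% for 3 against 3. In the libraries without epithelial transcripts, which are 2 WT mice and 1 113Q mouse, 3127 genes passed, a count that rests on a single 113Q library.

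**Figure D1:**
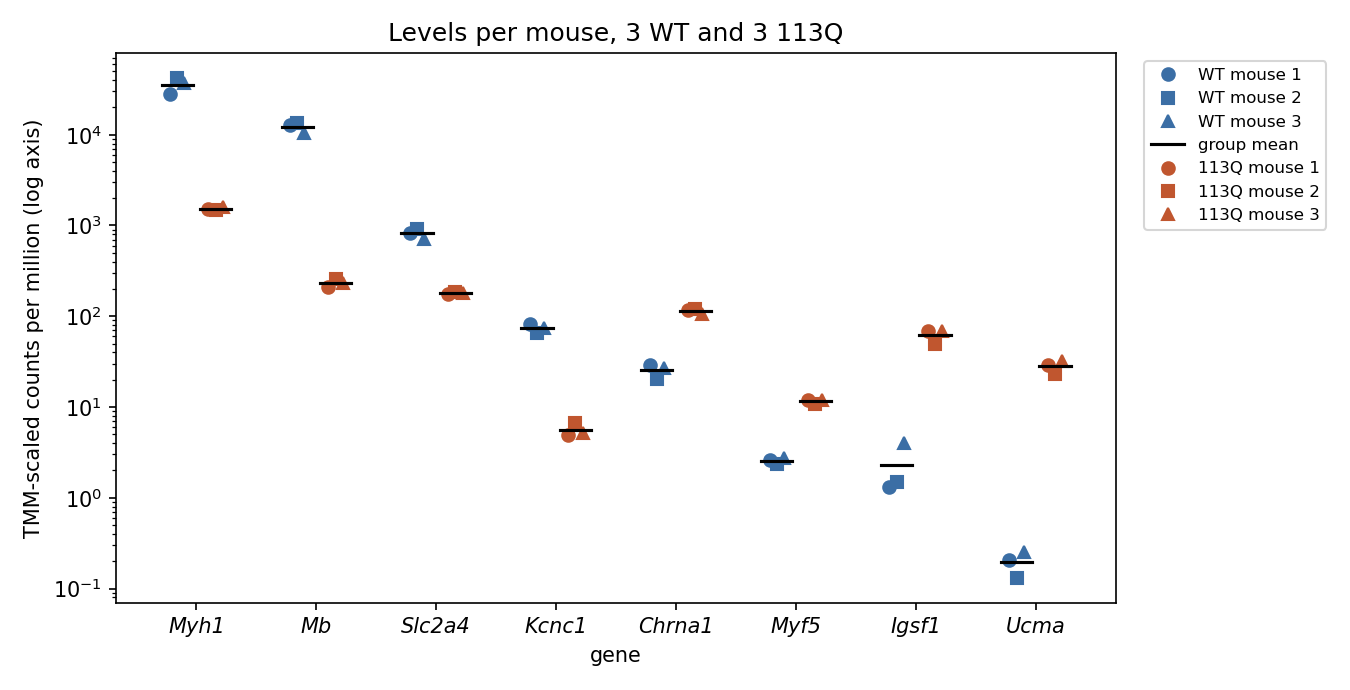
TMM-scaled CPM (log axis) of 8 genes in each of the 3 WT and 3 113Q mice, with symbols for mice and bars for group means. Myh1, Mb, Slc2a4 and Kcnc1 are lower in all 113Q mice, and Chrna1, Myf5, Igsf1 and Ucma are higher in all 113Q mice.

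All 19 members of the list of fast fibre sarcomere and calcium handling genes fell, and all 19 when adjusted over the list alone. Examples besides Myh1 are Myl1, a myosin light chain (log2 fold change -2.03), Mylpf, the fast regulatory light chain (-1.87), and Tnnt3, fast troponin T (-1.75). The median was -1.92 (camera adjusted p = 2.38e-14; adjusted p = 0.211 with an estimated correlation). All 11 limb-type myofibre markers fell, 11 adjusted over the list alone, with a median of -1.75 (camera adjusted p = 2.28e-08; adjusted p = 0.209 with an estimated correlation). Apart from Ttn and Neb, these markers are also members of the fast fibre list, so the lists are not independent. Of 14 slow fibre genes, 4 rose, 3 fell and 7 did not pass, and the counts adjusted over the list alone were 4 and 3. Atp2a2, the slow-type calcium pump, rose by 1.19 on the log2 scale, while Myl3, a slow myosin light chain whose exons overlap Pth1r on the other strand, had a log2 fold change of -4.41. The slow fibre list as a whole did not pass (camera adjusted p = 0.638, but 0.00198 as lower with library totals alone; range over alternatives 0.00198 to 0.95). Of 30 excitation-contraction coupling and ion channel genes, 19 fell, 1 rose and 10 did not pass; adjusted over the list alone, 20 fell and 3 rose. Kcnc1, a voltage-gated potassium channel, had a log2 fold change of -3.73, Casq1, the calcium buffer of the fast fibre, -1.23, and Clcn1, the muscle chloride channel, -1.07. The list passed at a camera adjusted p = 1.43e-06 (adjusted p = 0.533 with an estimated correlation).

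Of 30 glycolysis and glycogen genes, 26 fell, 2 rose and 2 did not pass, with 26 and 2 adjusted over the list alone (median log2 fold change -1.17). Aldoa, aldolase A, had a log2 fold change of -2.51, and Hk2, which phosphorylates glucose, -2.10. The list passed at a camera adjusted p = 2.94e-12 (adjusted p = 0.373 with an estimated correlation). Of 76 nuclear-encoded oxidative phosphorylation genes, 74 fell and 2 did not pass, with 74 adjusted over the list alone. Ndufs4, a complex I subunit, had a log2 fold change of -1.42 and Uqcrc1, a complex III subunit, -1.21. The median was -0.80 (camera adjusted p = 6.71e-24; adjusted p = 0.522 with an estimated correlation), and it was -0.08 with library totals alone. Of 26 genes of the tricarboxylic acid cycle and mitochondrial biogenesis, 18 fell and 8 did not pass, with 18 adjusted over the list alone. Idh3b, an isocitrate dehydrogenase subunit, and Ppargc1a, a coactivator of mitochondrial genes, had log2 fold changes of -1.32 and -1.10. Their median of -0.66 (camera adjusted p = 2.28e-08; adjusted p = 0.209 with an estimated correlation) was 0.06 with library totals alone. Relative to other genes, this list was still lower with that scaling (camera adjusted p = 2.99e-05). Of 30 fatty acid oxidation and lipid genes, 4 rose, 10 fell and 16 did not pass, with 6 and 10 adjusted over the list alone. Without WT mouse 1, 6 rose and 6 fell. Plin5, a lipid droplet protein, rose 5.37 times and Lpl, lipoprotein lipase, had a log2 fold change of -1.20. That list did not pass (camera adjusted p = 0.638). The list of mitochondrially encoded transcripts had 0 genes in the table.

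Of 25 denervation and neuromuscular junction genes, 10 rose, 4 fell and 11 did not pass, with 11 and 4 adjusted over the list alone. Ncam1, a cell adhesion molecule, rose 4.30 times, Runx1, a transcription factor, 4.28 times and Chrna1 4.57 times, while the perinatal myosin Myh8 had a log2 fold change of -1.29. The list as a whole did not pass (camera adjusted p = 0.0668; range over alternatives 0.0184 to 0.587), though it passed in some of them, such as voom (0.0184), without WT mouse 1 (0.0278) and with the filter of 1 CPM (0.0375). Of 10 satellite cell markers, 6 rose and 4 did not pass, with 6 adjusted over the list alone, among them Sdc4, a proteoglycan of the satellite cell, 2.29 times (camera adjusted p = 0.00307; adjusted p = 0.455 with an estimated correlation; 0.0559 with library totals alone; camera range over alternatives 0.00146 to 0.455). Of 24 myogenic and regeneration genes, 7 rose, 5 fell and 12 did not pass, with 7 and 5 adjusted over the list alone. Pax7, the satellite cell transcription factor, rose 1.79 times, and the list did not pass (camera adjusted p = 0.498). Myod1, another myogenic transcription factor, chosen after its values were seen, fell to 0.453 of its WT level (edgeR adjusted p = 0.00738). Of 21 cell cycle genes, 6 rose, 2 fell and 13 did not pass, with 6 and 3 adjusted over the list alone. Ccnd1, cyclin D1, rose by 0.74 and Rrm2, a subunit of ribonucleotide reductase, had a log2 fold change of -2.11 (camera adjusted p = 0.283).

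Transcripts of the protein quality machinery moved in both directions. Of 34 proteasome subunits, 24 fell and 10 did not pass, with 25 adjusted over the list alone, led by Psmd6 at -1.08 and Psmb2 at -0.79 on the log2 scale. The median of -0.42 (camera adjusted p = 1.82e-07; adjusted p = 0.546 with an estimated correlation) was 0.30 with library totals alone, where the list lost its call (adjusted p = 0.551; range over alternatives 2.32e-08 to 0.551). Of 27 endoplasmic reticulum stress genes, 15 rose, 3 fell and 9 did not pass, with 19 and 3 adjusted over the list alone. The disulfide isomerases Pdia4 and Pdia3 rose 2.11 and 1.68 times and the sensor Ern1 had a log2 fold change of -0.91. That list passed (camera adjusted p = 0.00143; adjusted p = 0.75 with an estimated correlation), and lost the call with library totals alone (adjusted p = 0.0559) and among the libraries without epithelial transcripts, where 113Q is 1 mouse (median 0.31 against 0.53 in all libraries, adjusted p = 0.14; range over alternatives 1.83e-06 to 0.75). Epcam was at or above 1 CPM in WT mouse 2 and in 113Q mice 2 and 3. Of 38 cytosolic chaperones, 10 rose, 15 fell and 13 did not pass, with 12 and 16 adjusted over the list alone (camera adjusted p = 0.498). Hspa4l and Hsph1, both relatives of the Hsp70 chaperones, rose 3.85 and 2.36 times, and the small heat shock protein Hspb7 fell to 0.462 of its WT level. Of 35 autophagy and lysosome genes, 5 rose, 4 fell and 26 did not pass, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.875, but 0.0201 as higher with library totals alone; range over alternatives 0.0201 to 0.999). Ctsb, the protease cathepsin B, rose 2.14 times. Of 23 atrophy-associated genes, 3 rose, 7 fell and 13 did not pass, with 3 and 7 adjusted over the list alone (camera adjusted p = 0.875). The ubiquitin ligase Trim63 fell to 0.502 of its WT level and the growth inhibitor Mstn to 0.390.

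Of 20 androgen and polyamine response genes, 8 fell, 2 rose and 10 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.213, but 0.0101 as lower with library totals alone; range over alternatives 0.0101 to 0.546). Mylk4, a kinase of the myosin light chain kinase family, had a log2 fold change of -2.56, Amd2, an enzyme of polyamine synthesis with the close copy Amd1, -2.18, and Smox, spermine oxidase, -1.85. The 2 genes that rose were Igf1r, a growth factor receptor, 1.76 times, and Odc1, also an enzyme of polyamine synthesis, 1.39 times. Odc1 was chosen after its values were seen. Of 82 cytosolic ribosomal protein genes, 39 fell, 1 rose and 42 did not pass, with 46 and 1 adjusted over the list alone. Without WT mouse 1, 25 fell and 1 rose. Rpl3l, the muscle form of Rpl3, had a log2 fold change of -1.29. The median of -0.34 (camera adjusted p = 6.14e-08; adjusted p = 0.75 with an estimated correlation) was 0.38 with library totals alone, where the call was lost (adjusted p = 0.587; range over alternatives 4.71e-09 to 0.75). Of 22 interferon response genes, 6 rose and 16 did not pass, with 6 adjusted over the list alone. Rsad2, an antiviral protein, rose 2.25 times and Irf7, an interferon regulatory factor, 1.95 times (camera adjusted p = 0.0109; adjusted p = 0.75 with an estimated correlation). That call was lost without 113Q mouse 2 (adjusted p = 0.0714), with library totals alone (adjusted p = 0.0559) and in the libraries without epithelial transcripts, where 113Q is 1 mouse (median 0.17 against 0.32 in all libraries, adjusted p = 0.0899); the camera range over alternatives was 0.00264 to 0.75.

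The other pathway lists did not pass the camera test as described, though some passed under other settings. Of 34 extracellular matrix genes, 4 rose, 1 fell and 29 did not pass, with 2 and 1 adjusted over the list alone (adjusted p = 0.0724, but 0.00457 without WT mouse 3 and 0.0335 without 113Q mouse 2; range over alternatives 0.00457 to 0.95). Timp2, a metalloproteinase inhibitor, rose 1.49 times. Of 40 splicing regulators, 1 rose, 6 fell and 33 did not pass, with 1 and 6 adjusted over the list alone (adjusted p = 0.388). Rbfox1 had a log2 fold change of -0.75. Of 30 growth factor and mTOR genes, 5 rose, 5 fell and 20 did not pass, with 5 and 5 adjusted over the list alone (adjusted p = 0.582). The cap-binding protein Eif4e had a log2 fold change of -0.92. Of 18 circadian clock genes, 1 rose, 6 fell and 11 did not pass, with 1 and 8 adjusted over the list alone (adjusted p = 0.0538, but 0.0463 with voom, 0.0284 with no filter, 0.0327 with the GC and length trend removed, and 0.0484, 0.0333 and 0.0281 without WT mouse 2, WT mouse 3 and 113Q mouse 2; range over alternatives 0.0281 to 0.546). Nr1d1, a repressor in the clock, fell to 0.499 of its WT level. Of 22 immediate early genes, 2 rose, 4 fell and 16 did not pass, with 1 and 4 adjusted over the list alone (adjusted p = 0.498, but 0.0264 with library totals alone and 0.000697 in the libraries with epithelial transcripts, where WT is 1 mouse; range over alternatives 0.000697 to 0.971). Jun had a log2 fold change of -1.19. The sex marker list did not pass (adjusted p = 0.996).

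All 12 endothelial markers fell, 12 adjusted over the list alone, with Pecam1, an adhesion molecule of vessels, at 107.0 ± 10.2 CPM in WT and 61.6 ± 1.01 CPM in 113Q. Their median log2 fold change of -0.66 (camera adjusted p = 1.44e-05; adjusted p = 0.522 with an estimated correlation) was 0.07 with library totals alone. Relative to other genes, the endothelium list was still lower with that scaling (camera adjusted p = 0.0101). Of 13 smooth muscle and pericyte markers, 2 rose, 1 fell and 10 did not pass, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.283). Abcc9, a potassium channel regulator, rose 1.30 times. Acta2 also passed (edgeR adjusted p = 0.037), chosen after its values were seen, and it lost the call without WT mouse 2 (adjusted p = 0.113) and without any 113Q mouse (adjusted p = 0.0845, 0.095 and 0.0619; range over alternatives 0.000195 to 0.447). Of 12 fibroblast markers 0 passed in edgeR in either count, with 3 at an unadjusted p below 0.05, 3 in DESeq2 and 0 in voom (camera adjusted p = 0.459). Of 9 tenocyte markers 0 passed in edgeR in either count, with 2 at an unadjusted p below 0.05, 1 in DESeq2 and 0 in voom (camera adjusted p = 0.498). Of 15 macrophage markers 2 rose, with 0 adjusted over the list alone (camera adjusted p = 0.402). Of 12 adipocyte markers, 1 rose, which was Cidea, and 1 fell, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.997). In the fits to libraries with or without epithelial transcripts, 1 group is a single mouse; the adipocyte median was 2.68 and -1.72 and the tenocyte median -1.62 and 1.76 in these fits, values that rest on single libraries. Of 12 Schwann cell markers, 2 rose and 1 fell in both counts (camera adjusted p = 0.875). Those that rose, Sox10 and Pmp22, lost the call without WT mouse 1 (edgeR adjusted p = 0.0658 and 0.0914). They also lost it without WT mouse 2 (edgeR adjusted p = 0.0673 and 0.0919). Sox10 further lost it without WT mouse 3, 113Q mouse 2 and 113Q mouse 3 (edgeR adjusted p = 0.0747, 0.0752 and 0.0818). Pmp22 further lost it without 113Q mouse 1 and 113Q mouse 3 (edgeR adjusted p = 0.0938 and 0.08). Of 7 lymphocyte markers 1 rose, of 14 epithelial and gland markers 1 fell and of 4 cartilage and bone markers 1 rose, with 0 of each adjusted over the list alone (camera adjusted p = 0.459, 0.996 and 0.638; the epithelial list passed as lower with library totals alone at 0.0101, with a range over alternatives of 0.000704 to 0.999). Of 8 neutrophil and mast cell markers and 5 blood markers 0 passed in edgeR in either count, at an unadjusted p below 0.05, in DESeq2 or in voom (camera adjusted p = 0.962 for both).

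**Figure D2:**
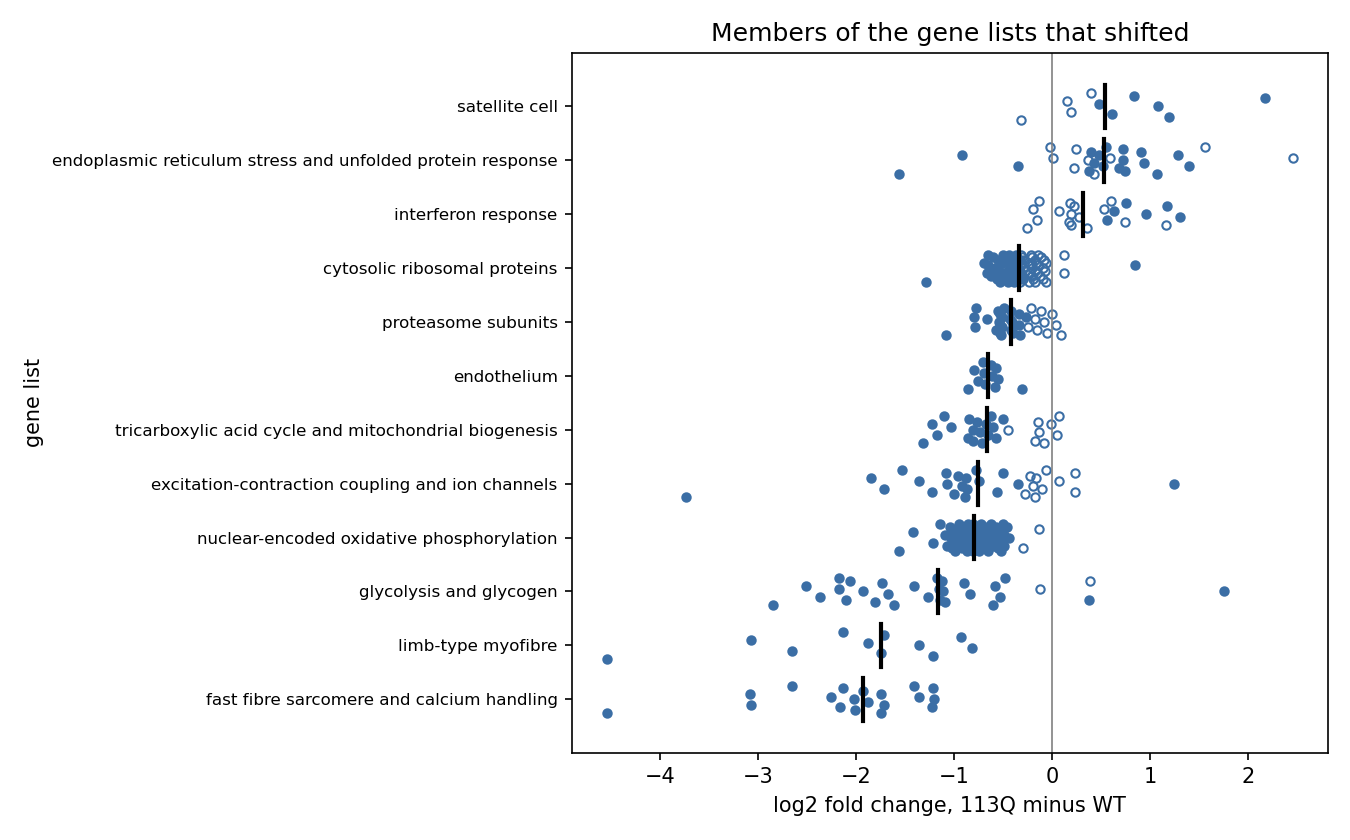
Log2 fold change (113Q minus WT) of each member of the 12 lists that passed with camera at its preset correlation; filled points passed the edgeR test, open points did not, and bars mark list medians. All points of the fast fibre, limb-type myofibre and endothelium lists lie below 0. With library totals alone the medians of the proteasome, ribosomal, tricarboxylic acid cycle and endothelium lists lie above 0. That scaling moves the median of all genes by 0.72, and camera still called the tricarboxylic acid cycle and endothelium lists lower there.

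**Figure D3:**
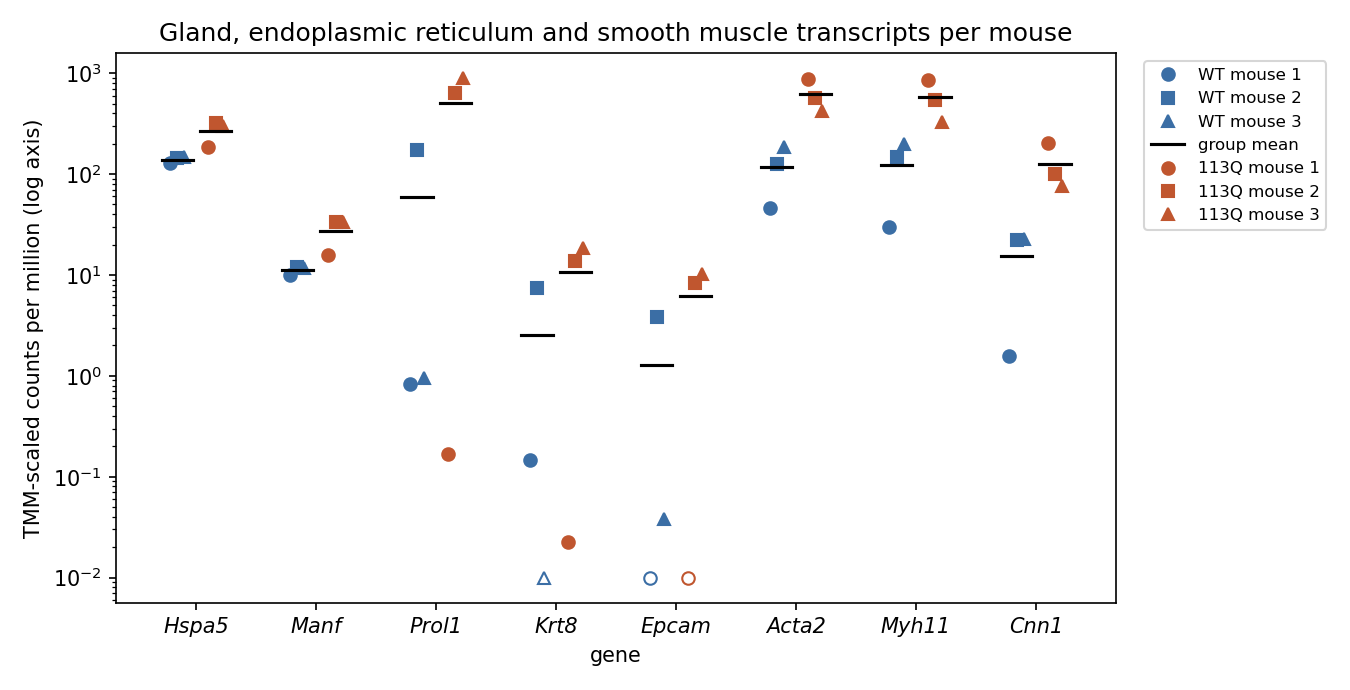
TMM-scaled CPM (log axis) per mouse of 8 genes of the endoplasmic reticulum, glands, epithelium and smooth muscle, with bars for group means; open symbols at the lower edge mark 0 counts. Epcam is at 3.83 CPM in WT mouse 2, 8.29 in 113Q mouse 2 and 10.2 in 113Q mouse 3, and at or below 0.0385 in the other libraries.

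Among genes with the largest rises, Ucma, a secreted protein first described in cartilage, went from 0.197 ± 0.0598 to 28.2 ± 4.78 CPM (edgeR adjusted p = 2.2e-06), and Bbox1, an enzyme of carnitine synthesis, rose 66.8 times. Arhgap36, Igsf1, Klhl13 and Gprasp2 rose 50.7, 27.0, 10.4 and 10.5 times and are all on chromosome X. Without WT mouse 3 the folds of Arhgap36 and Igsf1 were 86.5 and 44.2. Exons of Gprasp2 overlap Bhlhb9 on the same strand, so their reads may be shared. Pln, a regulator of the slow calcium pump, rose 24.7 times and overlaps Cep85l on the other strand. Among the largest falls, Hamp2, a hepcidin family gene with a close copy, fell from 2595 counts over the WT libraries to 11 over the 113Q libraries (7 of them in 113Q mouse 1), Fscn2, an actin bundling protein, fell 120.7 times and Cacna1e, a calcium channel subunit, 76.2 times. Without 113Q mouse 3 the fold of Fscn2 was 183.6, and without 113Q mouse 1 that of Cacna1e was 114.8. Cyp17a1, a steroid synthesis enzyme, had 1659 counts over the WT libraries and 2 over the 113Q libraries, a ratio of 0.000614 after scaling to TMM library sizes (95% counting interval 7.43e-05 to 0.00222), with 28.0 CPM in WT mouse 2 against 2.81 and 1.52 in the other WT mice. Without WT mouse 2 that ratio was 0.00362 (0.000435 to 0.0133), and both 113Q counts were in 113Q mouse 2. Its call was lost without each 113Q mouse in turn (edgeR adjusted p = 0.0805, 0.171 and 0.0933; range over alternatives 7.08e-07 to 0.171). The sources used here do not say whether strands were told apart; if they were not, reads of Mb and Myh1 may be shared with Apol6 and Myhas on the other strand. The myosin heavy chain genes are close copies of each other.

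Of the 12 lists that passed with camera, 0 passed with an estimated correlation (4 of the 38 lists had an unadjusted p below 0.05 there), and 16 lists passed with fry, which does not compare a list with other genes. Some of the 12 lists share members, as the fast fibre and limb-type myofibre lists do, so they are not separate results. In the 9 other ways to divide the 6 libraries into groups of 3, which mix the genotypes, camera at the preset correlation called 11 to 17 lists, while edgeR called at most 3 genes. Mixing adds the genotype difference to the spread within groups and leaves part of it between groups. Neither count therefore measures chance.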

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

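The tests of myofibre share, library scaling and epithelial tissue were chosen after the results they bear on were seen, and the excess on chromosome X was first noticed among the largest rises and then tested on the same data. No rule for outlying samples or for differences between contrasts was applied, as each group holds 3 mice and there is a single contrast.

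Fast fibre, glycolysis and oxidative phosphorylation transcripts were lower in 113Q. A smaller share of myofibre RNA would raise markers of the other cell types alike, if these cell types did not change themselves. The fibroblast median lay above the endothelium median by 0.918 on the log2 scale, more than the summed SDs over members (0.447). These medians were 0.982 and 0.066 with library totals alone. A separate change in endothelium would also give this gap, so it cannot decide on the share of myofibre RNA. With library totals alone the fast fibre median stayed at -1.20, and with the GC and length trend removed the medians were -1.83 for fast fibre and -0.67 for oxidative phosphorylation, which argues against scaling for the fast fibre list and against that trend for both. For oxidative phosphorylation, the median was -0.078 with library totals alone (SD over members 0.23), a scaling that moves all genes by 0.72. The size of that fall thus depends on the scaling. Neither scaling measures absolute level, so whether the absolute level fell cannot be told. Relative to other genes the list was lower with library totals too (camera adjusted p = 1.82e-22; 0.522 with an estimated correlation and TMM factors). A smaller share of myofibre RNA stays open, as do, as hypotheses, a change in fibre programme with the genotype and a change in the other cell types. No test of a change in fibre programme was run.

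The endoplasmic reticulum stress list was higher in 113Q, and epithelial transcripts were present in WT mouse 2 and in 113Q mice 2 and 3. Its median of 0.53 was 0.42 with a term for those libraries (camera adjusted p = 0.00302; adjusted p = 0.75 with an estimated correlation and no such term) and 0.312 among the libraries without them (camera adjusted p = 0.14; SD over members 0.673; range over alternatives 1.83e-06 to 0.75), where a single 113Q library is left. Hspa5, Creld2 and Manf, chosen after their values were seen, were at 184, 10.1 and 15.9 CPM in 113Q mouse 1, which holds no Epcam, against 139.3 ± 9.54, 6.64 ± 1.63 and 11.3 ± 1.11 in WT (n = 3), and at 318, 23.0 and 33.5 in 113Q mouse 2. All 3 were thus above every WT mouse in a 113Q mouse without Epcam, so epithelium need not be the whole source, though this rests on 1 mouse. WT mouse 2, with Epcam, was near WT mouse 3 for Hspa5 and Manf. For Creld2 it was the highest WT mouse (8.1 CPM, against 4.89 and 6.95 in WT mice 1 and 3). It held less Epcam (3.83 CPM) than 113Q mice 2 and 3 (8.29 and 10.2 CPM), so its values decide little. Each gene lost its call without WT mouse 1 (edgeR adjusted p = 0.054, 0.0711 and 0.0689). Creld2 also lost it without WT mouse 3 (0.0688) and 113Q mouse 3 (0.0585), and Manf without WT mice 2 (0.052) and 3 (0.0547). The edgeR ranges over alternatives were 2.77e-06 to 0.0893, 1.05e-05 to 0.108 and 2.76e-06 to 0.119. Secretory epithelium is a candidate source of part of this rise, and it cannot be told apart from an effect of genotype because the libraries are few: 1 WT mouse holds it and 1 113Q mouse does not.

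Of 550 tested X-linked genes, 56 (10.2%) were at least 2 times higher in 113Q, against 5.19% of autosomal genes (odds ratio 2.07, 95% 1.53 to 2.76; Fisher's exact test across genes, which are not independent, adjusted p = 8.6e-05 over 20 chromosomes). It was the only chromosome to pass for genes at least 2 times higher, and the share on X exceeded that on autosomes under library totals, RLE and upper-quartile factors, the GC and length trend and the epithelial term (odds ratios 1.58 to 2.23). A higher level of the whole chromosome may contribute, since the X median exceeded the autosomal median by 0.163, between the bounds set for and against it. It cannot be told apart from an effect of genotype on separate X-linked genes with a single comparison in the data.

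Of the 10 ways to divide the 6 libraries into groups of 3, 1 gave as many genes as the real division (5869; highest other 3), and 9 gave as many lists (12; highest other 17). With 10 divisions a share under 0.05 cannot be reached. The list medians were 1.92 in size for fast fibre (highest other 0.65), 0.337 for ribosomal proteins (0.222), 0.527 for endoplasmic reticulum stress (0.404) and 0.316 for interferon (0.237). The fast fibre list was called in all 9 other divisions. Each other division holds both genotypes in each group, in unequal numbers, so part of the genotype difference stays between its groups. The rest adds to the spread within groups, which lowers the number of genes called. These divisions therefore do not measure chance, and cannot decide whether the camera calls at the preset correlation reflect the genotype.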

How the results depend on the processing

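The tests on libraries with or without epithelial transcripts and on GC content and length were chosen after seeing the data; the others were planned. The count of 5869 genes was 11725 with library totals alone, 3127 in the libraries without epithelial transcripts (2 WT mice, 1 113Q mouse), 3424 at an adjusted p below 0.01 and 3793 against a fold of 1.2; leaving out each mouse gave 4325 to 5402. Of the 5869 genes, 1669 changed sign with library totals alone and 0 in the other refits. The 12 lists became 0 with an estimated correlation, and leaving out each mouse gave 12 to 14.

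Of 138 genes checked, 81 kept direction and call throughout and 119 kept direction; 20 lost the call without some mouse. With library totals alone the sign turned, with log2 fold changes of 0.0261 for Eif4ebp1, 0.15 for Psmd12, 0.12 for Wipi1, 0.11 for Acat1, 0.22 for Etfa, 0.10 for Rplp2, 0.0219 for Rplp0, 0.0702 for Rpsa, 0.34 for Col4a2, 0.16 for Rbm24, 0.24 for Mbnl1, 0.0845 for Tef, 0.23 for Per3, 0.22 for Mcm2, 0.0349 for Fabp4, 0.10 for Esam, 0.28 for Des, 0.27 for Tgm4 and 0.60 for Ddx3y; that setting moves all genes up by 0.72. Only among libraries with epithelial transcripts was Ddx3y at 0.0245; the cause was not tested. Igj and Dmp1 had no value under the filter of 1 CPM in 3 mice.

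The mouse numbers are shared by both groups, and the labels do not say that they pair mice. Deviations of same-numbered mice from their group means correlated at 0.198, 0.236 and -0.274, and not every mouse correlated best with its own number. With 3 mice per group these values cannot decide on pairing. With a replicate block, 4737 genes and 13 lists passed. Depth was ample for abundant transcripts, and changes under 2 times were often missed in simulation.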

Other observations

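The genes in this part, the potassium channel family and their tests were chosen after their values were seen. Several potassium channel subunits were far lower in 113Q: Kcnf1 went from 32.6 ± 4.77 to 1.41 ± 0.469 CPM (n = 3 each), Kcng4 from 236.6 ± 1.86 to 14.5 ± 4.97 CPM and Kcnq5 from 98.2 ± 5.76 to 6.49 ± 1.56 CPM, all past the edgeR threshold. The family did not move as a whole: of 52 tested genes with symbols starting with Kcn, 7 rose, 12 fell and 33 did not pass (camera p = 0.338; p = 0.544 with an estimated correlation). The abundant transcripts Car3, a carbonic anhydrase of muscle, and Aqp4, a water channel of fast fibres, were 5.79 and 4.70 times lower in 113Q. Fkbp5, a known androgen-responsive gene, was 7.18 times lower, or 4.69 times without WT mouse 2, with 340 CPM in WT mouse 2 against 125 and 137 in the other WT mice.

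Among X-linked genes, Tceal5 rose 8.38 times, Bex1 7.24 times and Gprasp1 4.36 times. Myh1 made up 2.78% ± 0.543 of all counts in WT and 0.196% ± 0.00572 in 113Q, and Myh8 2.91% ± 0.171 and 1.96% ± 0.164. The gland transcript Prol1 was at 0.829, 174 and 0.943 CPM in WT and 0.167, 638 and 896 CPM in 113Q, the libraries that also held Epcam. The smooth muscle gene Myh11 was at 124.1 ± 85.5 CPM in WT and 578.8 ± 270.5 CPM in 113Q, Cnn1 was at 1.57, 22.2 and 22.6 CPM in WT and 202, 100 and 76.5 CPM in 113Q, and neither passed (edgeR adjusted p = 0.111 and 0.0952).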
